A study of Mus musculus with 6 samples.

How the data were processed

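Gene expression was measured in 3 thymic and 3 thyroid samples of sorted mouse epithelial cells. RNA was extracted with Trizol and labelled with Cy3, per the labels' protocols. The arrays were scanned and read with Agilent Feature Extraction 10.5.1.1, per the file headers, which place the probes on the mm8 genome build. Per the file headers, the deposited scanner files give each spot's brightness as an intensity: a processed signal that is detrended and background-subtracted, with a surrogate where a spot is not above background, and the raw mean and local background signals. The authors also deposited a value table, which is a linear ratio: set against the scanner values, each column equals the processed signal divided by that array's median, with a median of 1 in every column. Its direction and scale are thereby known, and no column was left unused.

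Each array held 43379 non-control spots for 41174 probes. Control spots and the 67 to 151 outlier spots per array were left out, spots of a probe were averaged, and a flag was taken as set where at least 50% of a probe's spots had it. The main values were log2 of the processed signal minus each array's 75th percentile. A probe was tested if well above background on all 3 arrays of at least 1 group, a flag that the scanner software set here with a multiple of 13 background SDs. From here on, above background stands for this flag. Gene names were taken from a mouse table of the GRCm38.p6 assembly, used for names and gene order only: 24375 probes matched by accession, 6301 by symbol and 2426 by a unique older symbol, and 8072 kept the name in the file. A gene was represented by its tested probe with the highest mean level. Of 7411 genes with several tested probes, 368 had probes past the threshold in opposite directions.

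The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. Some folds of named genes are against a group with arrays on which the probe was not well above background. These are called lower bounds here and printed as "at least". They set the bright group's mean against a floored mean of the dim group. Per array, the floored value is the higher of the lowest signal well above background and the probe's own. Such a bound is no strict minimum. Where the probe's own signals are the higher ones, it equals the plain fold, as for Stfa3 (113-fold). Lists with 5 or more tested members were tested with camera at an inter-gene correlation of 0.01, adjusted over the 28 lists, with an estimated correlation and fry beside it. Fry tests whether the genes of a list move, on balance, in a single direction and compares no list with other genes. The lists came from textbook knowledge, none from these samples, and were fixed before the data were examined, as were the tests of the groups and of the lists, the rule for named genes and, with the exceptions named below, the other ways of processing. That rule took the 6 largest differences per direction among genes above background on all 6 arrays whose groups do not overlap, the 4 largest lower bounds per direction, up to 2 members per direction in each list, and 18 genes named whatever their values. Predicted and Riken symbols were counted but not named, and 1 gene that the rule takes is not reported here.

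The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the deposited value table, no filter or a filter on all 6 arrays, the median over a gene's probes, the slide as a block, slide 1 alone, a replicate block, trended and robust variances, array weights and leaving out each replicate. Chosen after seeing the data were scaling by the median of probes above background on all arrays, leaving out both replicates 3, and leaving out the 62 probes that the array files place on another chromosome than the gene they are named after, which represented 24 genes. Thymic replicates 1 to 3 and thyroid replicate 1 shared slide 1, and thyroid replicates 2 and 3 slide 2. On slide 1 alone, the single thyroid array is assumed to vary like the thymic arrays. The fit was tested on simulated data with 200 of 21381 genes changed. There, 1.49% of genes changed by 0.5 on the log2 scale were recovered, 64.2% of those changed by 1 and 95.5% of those changed by 2. In the simulation 5 unchanged genes were called. In the data 69.8% of genes passed, which makes the adjusted threshold looser than in the simulation. The simulated shares therefore do not carry over to the data, where smaller differences pass more often. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.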

Results

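RNA from sorted mouse epithelial cells of the C57BL/6 strain was measured on 6 single-colour Agilent arrays. The thymic cells came from the medulla, the inner zone of the thymus in which maturing T cells meet tissue antigens, and were sorted as alive, positive for Epcam (an epithelial adhesion protein) and for the lectin UEA1, and negative for CD45, the surface protein of blood cells. The thyroid cells were sorted as alive, Epcam-positive and CD45-negative. Each group held 3 arrays, which the submitters call independent replicates. Thymic replicates 1 and 2 each pooled 6 thymi, thymic replicate 3 pooled 2, and each thyroid replicate pooled 20 thyroids. The signal at the 75th percentile was 772, 700 and 676 on the thymic arrays and 805, 476 and 712 on the thyroid arrays, and no spot was saturated. With 3 arrays per group, their number limits the precision.

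The comparison of the groups asked which genes differ between thymic and thyroid epithelial cells. Among genes measured above background on every array, the largest differences towards the thymic cells belonged to Cyp2a5, a cytochrome P450 known from the liver (6589-fold), Ccl21c, a chemokine gene (1948-fold), Wfdc18 (1339-fold), Fcgbp (746-fold), Slc46a2 (664-fold) and Gjb2, a gap junction gene (642-fold). Towards the thyroid cells they included Emcn (2942-fold), Kdr (1784-fold), Esm1 (1077-fold) and Tie1 (1063-fold), all known from endothelium, and Tg, which encodes thyroglobulin (1755-fold). The adjusted p of these genes, by limma with the Benjamini-Hochberg method, lay between 2.04e-07 for Tg and 1.08e-04 for Ccl21c. In each of them the 3 values of a group lay apart from those of the other, as the rule that named them required. Some dim groups lay close to background: Cyp2a5 at -5.77 and Gjb2 at -5.05 in thyroid cells, and Tie1 at -5.57 in thymic cells. Ccl20, above background on no thyroid array, was at -5.99 there. Such folds rest on faint signals and are less certain than their digits show. The dim means of the others were -4.71 (Slc46a2) or higher. The difference of Ccl21c depended on the array left out, with 808-fold without thyroid replicate 3 and 3942-fold without thyroid replicate 1. Ccl21a, a member of the medullary and chemokine lists, was not measured under its own name. Whether the probe of Ccl21c also reads Ccl21a was not tested. Among genes not well above background on any thyroid array, Reg3g, which encodes an intestinal antimicrobial lectin, was at least 9800.2-fold higher in the thymic cells (adjusted p = 9.77e-07), Lypd8 at least 2099.7-fold, Ccl20 at least 1322-fold and Fgf21 at least 1217-fold. In the opposite direction, Adgrl4 was at least 587-fold, Clec14a at least 483-fold, Pax8 at least 134-fold and Tshr at least 91.7-fold higher in the thyroid cells.

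Of 21381 genes tested, 8402 were higher in thymic and 6515 higher in thyroid epithelial cells at an adjusted p under 0.05, and 6071 and 3144 of these differed 2-fold or more. The 2-fold counts were 3573 and 2404 with normexp background correction, 2758 and 2832 with only probes above background on all 6 arrays, and 4890 and 5853 with median centring. The 3 values of a group did not overlap those of the other for 16348 genes, or 76.5%, where chance gives 10%. Differences of 8-fold or more numbered 2925 towards the thymic and 659 towards the thyroid cells, and 2082 and 604 with arrays not above background set to their floor. With the slide as a block, 7730 genes were higher in thymic and 5533 in thyroid cells, and within slide 1, which held all thymic arrays and thyroid replicate 1, 8387 and 6145 were. The balance of the 2 directions depended on the scaling and the filter. With the 75th percentile, 56.3% of the calls were higher in thymic cells. The share was 48.0% (7287 against 7905) with quantile normalization and 44.0% (5032 against 6403) with only probes above background on all 6 arrays. It was 35.6% (6098 against 11041) with median centring and, for the deposited values, 35.8%. Median centring shifted all genes by -0.54 on the log2 scale and quantile normalization moved them by unequal amounts with a median of -0.19, so smaller differences are relative to the scaling. At 2-fold or more, 65.9% of calls were higher in thymic cells, against 55.0% with quantile normalization, 49.3% with the filter on all 6 arrays and 45.5% with median centring.

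Genes that define the sort and the lineages differed between the groups. Epcam was 2.36-fold higher in thymic cells, at a log2 level of 2.96 ± 0.15 against 1.72 ± 0.34 (SD, n = 3 each, limma adjusted p = 0.00109). Ptprc, which encodes CD45, stood at -0.86 ± 0.46 in thymic and -4.91 ± 0.17 in thyroid cells, a 16.6-fold difference (limma adjusted p = 1.04e-05), although both sorts excluded CD45-positive cells. Aire, the regulator of antigen expression in the medulla, was at 6.13 ± 0.16 in thymic cells and above background on 2 of the 3 thyroid arrays, at -5.95 ± 0.45. Fezf2, a transcription factor of the same cells, was at least 853-fold higher in thymic cells (adjusted p = 3.91e-07). Foxn1, which thymic epithelium needs to develop, was 26.4-fold higher (adjusted p = 7.44e-06). The probe of Aire lies at chromosome 10, 77433207 to 77433266, that of Fezf2 at chromosome 14, 11135810 to 11135869, and that of Tg at chromosome 15, 66680185 to 66680244, in the mm8 coordinates of the array files.

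**Figure D1:**
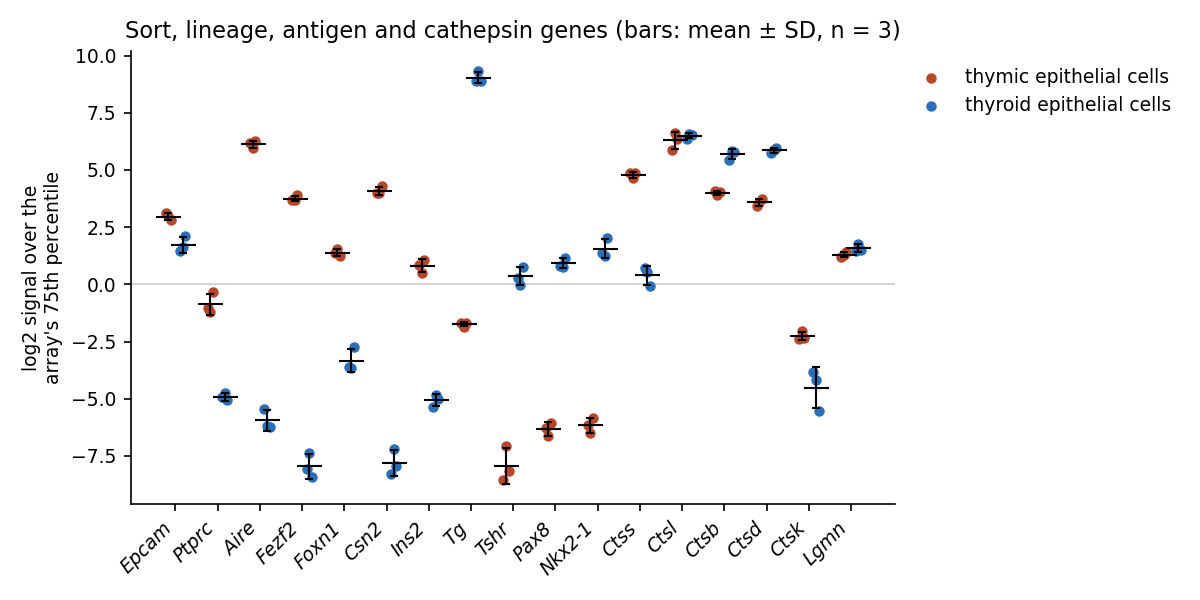
Log2 signal relative to the array's 75th percentile (vertical axis) of genes of the sort, the lineages, tissue antigens and cathepsins (horizontal axis), with 1 point per array in red for thymic and blue for thyroid cells and bars for the mean ± SD of 3 arrays. Levels compare the groups within a gene, not genes with each other: Aire stands at 6.13 in thymic and -5.95 in thyroid cells, Tg at -1.74 and 9.04, and Ctsl at 6.29 and 6.51.

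Genes of the thyroid follicular cell, which makes thyroid hormone, were lower in the thymic cells as a list: 16 of 23 tested members were higher in thyroid cells, 4 higher in thymic cells, and the median log2 difference (thymic minus thyroid) was -4.42, or -4.16 on slide 1 (camera adjusted p = 1.15e-05, and adjusted p = 0.371 with an estimated correlation). Tg stood at 9.04 ± 0.24 in thyroid and -1.74 ± 0.09 in thymic cells (SD, n = 3). Nkx2-1, a transcription factor of the thyroid, was at least 197-fold higher in thyroid cells (adjusted p = 1.02e-06) and well above background on 2 of 3 thymic arrays. The 4 members higher in thymic cells included Slc26a4, the iodide and chloride exchanger pendrin (28.1-fold, adjusted p = 2.73e-05), and Kcne2, a potassium channel subunit, at least 28.0-fold. On the thymic arrays, 19 of the 23 members were well above background on all 3 arrays, and 12 of the members higher in thyroid cells were among these, Tg included. Of all 41174 probes, 78.4% to 81.0% were well above background on a thymic array, so detection alone does not set this list apart. Pax8 and the thyrotropin receptor gene Tshr were well above background on no thymic array. By a weaker flag of the software, for a signal positive and significant against background, Pax8 and Nkx2-1 were detected on 3 thymic arrays and Tshr on 1.

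Medullary thymic genes were higher in the thymic cells in 24 of 26 tested members, with 1 higher in thyroid cells, a median of 5.69 (6.19 on slide 1) and a camera adjusted p of 7.91e-08 (adjusted p = 0.159 with an estimated correlation). Ltbr, the lymphotoxin receptor gene, was the member higher in thyroid cells, by 1.76-fold (adjusted p = 0.00988). Cortical thymic genes did not pass as a list (median 3.58, 3.61 on slide 1, camera adjusted p = 0.228), although median centring gave an adjusted p of 0.0355 and the deposited values an adjusted p of 0.0366, in a range over the alternatives of 5.86e-04 with fry to 0.591 with an estimated correlation. In that list 8 of 12 members were higher in thymic cells, among them the chemokine gene Ccl25 (158-fold) and the cytokine gene Il7 (at least 112-fold, above background on 2 thyroid arrays). Higher in thyroid cells were 3, among them Cxcl12 (log2 difference -4.25) and Kitl (16.2-fold). All 13 endothelial genes also were (median -7.28), and the share of endothelial cells in these differences was not separated.

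Tissue-restricted antigens, genes known from other organs that medullary cells are described to express, were higher in thymic cells in 45 of 51 tested members and higher in thyroid cells in 3. Their median difference was 5.97, or 6.03 on slide 1 and 5.15 with 27 members at their bound (camera adjusted p = 1.39e-09, and adjusted p = 0.237 with an estimated correlation). The milk casein gene Csn2 was at least 1074-fold higher in thymic cells (adjusted p = 4.12e-07), and Ins2, an insulin gene, was 58.8-fold higher (adjusted p = 1.09e-06). S100b and Npy, known from the nervous system, were 32.3-fold and 4.66-fold higher in thyroid cells. Cornified keratinocyte genes, which build the outer epidermis, were higher in thymic cells in 27 of 28 members (median 5.10, 5.46 on slide 1, 4.35 with 13 members at their bound, camera adjusted p = 3.60e-09, and adjusted p = 0.159 with an estimated correlation), with Calm4 at least 440.2-fold and Krtdap at least 432-fold higher. All 13 tested genes of tuft cells, the chemosensory cells of mucosal epithelia, were higher in thymic cells (median 4.77, 5.30 on slide 1, camera adjusted p = 5.17e-06, and adjusted p = 0.159 with an estimated correlation). Gng13 was at least 1102-fold and the cation channel gene Trpm5 at least 329-fold higher, each above background on 1 thyroid array.

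Antigen presentation by MHC class II was higher in thymic cells in all 12 tested members (median 5.30, 5.45 on slide 1, camera adjusted p = 5.07e-06, and adjusted p = 0.243 with an estimated correlation). H2-Oa was 317-fold and Ciita, the class II transactivator, 130.2-fold higher. Genes of blood cells that carry class II moved the same way, with 8 of 8 B-cell and 14 of 16 myeloid and dendritic genes and Ptprc (16.6-fold) higher in thymic cells. Their share in the class II difference was not separated. MHC class I processing genes did not pass as a list (camera adjusted p = 0.885), with 5 of 15 members higher in thymic and 4 in thyroid cells. Their median was 0.25, -0.11 on slide 1 and -0.29 with median centring, and camera's direction was towards the thyroid. Calr, Canx and Pdia3, all higher in thyroid cells, are also in the list of endoplasmic reticulum chaperones. Without such shared members, the median was 0.45 over 12 members and the direction was towards the thymic cells (camera adjusted p = 0.451). Psmb9 and Psmb10, subunits of the immunoproteasome, were 2.04-fold and 1.96-fold higher in thymic cells (adjusted p = 0.00343 and 0.00266, and 0.0648 and 0.0682 with median centring, the highest over the alternatives, where the lowest were 5.96e-04 and 4.23e-04).

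Endolysosomal proteases went in both directions, with 7 of 20 members higher in thymic and 9 in thyroid cells (median -0.25, -0.12 on slide 1, mean 0.15, camera adjusted p = 0.332 towards the thyroid, in a range of 0.00293 with fry to 0.841). Higher in thymic cells were Prss16, a serine protease of the thymic cortex (67.3-fold), Ctss, which encodes cathepsin S (log2 difference 4.40, adjusted p = 4.56e-06), and Ctsk (4.76-fold, adjusted p = 0.00290). Napsa (20.3-fold), the cathepsin D gene Ctsd (4.85-fold, adjusted p = 7.36e-06) and the cathepsin B gene Ctsb (3.24-fold, adjusted p = 5.44e-05) were higher in thyroid cells. Ctsl, which encodes cathepsin L, stood at 6.29 ± 0.37 in thymic and 6.51 ± 0.11 in thyroid cells (SD, n = 3, limma adjusted p = 0.367), and its difference of -0.22 turned to 0.03 with quantile normalization and passed at -0.75 with median centring (adjusted p = 0.0118, in a range of 0.0118 to 0.936 over the alternatives). Lgmn, the legumain gene, differed by -0.28 (adjusted p = 0.0960), and by -0.82 with median centring (adjusted p = 8.17e-04, in a range of 8.17e-04 to 0.479). Cystatin and related inhibitors of proteases were higher in thymic cells in 11 of 14 members (median 2.90, 2.93 on slide 1, camera adjusted p = 0.0158, and adjusted p = 0.237 with an estimated correlation). Spink5 was at least 531-fold and Stfa3 at least 113-fold higher there, above background on 1 and 2 thyroid arrays, while Timp3 (7.64-fold) and Cst3 (2.77-fold) were higher in thyroid cells.

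Chemokine genes were higher in thymic cells in 15 of 19 members (median 4.71, 5.01 on slide 1, camera adjusted p = 5.82e-04, and adjusted p = 0.386 with an estimated correlation), with Ccl19 445-fold higher and Cxcl12 and Cx3cl1 higher in thyroid cells at log2 differences of -4.25 and -1.28. Genes of blood cells, which make some of these chemokines, moved the same way, with 15 of 17 thymocyte, 14 of 16 myeloid and 8 of 8 B-cell genes higher in thymic cells. Their share in the chemokine difference was not separated. The call of Cx3cl1 ended with the median over its probes (adjusted p = 0.0552, in a range of 2.16e-06 to 0.0552). TNF receptor and NF-kB signalling genes were higher in thymic cells in 18 of 24 members (median 1.02, 0.96 on slide 1, camera adjusted p = 0.00666, and adjusted p = 0.237 with an estimated correlation). Tnfrsf11a, which encodes the receptor RANK, was 18.7-fold higher. The blood-cell genes above moved the same way as this signalling list, and their share in its difference was not separated. Interferon-stimulated genes, with 4 of 19 members higher in thymic and 6 in thyroid cells, did not pass (median -0.31, camera adjusted p = 0.332), and without thyroid replicate 1 their median was 0.10. On slide 1 alone they were at -0.72 (adjusted p = 0.00927, and 0.0222 with the slide as a block), in a range of 0.00927 to 0.992 over the alternatives. Rsad2 was 12.8-fold higher in thyroid and Cxcl10 5.51-fold higher in thymic cells.

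Cell cycle genes were higher in thymic cells in 24 of 29 members (median 2.06, 2.22 on slide 1, camera adjusted p = 3.28e-04, and adjusted p = 0.425 with an estimated correlation). Genes of blood cells moved the same way, with 15 of 17 thymocyte and 8 of 8 B-cell genes and Ptprc (16.6-fold) higher in thymic cells. Their share in this difference was not separated. Top2a was 25.4-fold higher and Bub1 at least 19.5-fold, whereas Pcna, the replication clamp, was 2.48-fold higher in thyroid cells. General epithelial genes were higher in thymic cells in 13 of 18 members, with a median of 0.87 (1.09 on slide 1) and a camera adjusted p of 0.0310. That call ended with median centring (adjusted p = 0.0539), with the deposited value table (adjusted p = 0.0522) and with an estimated correlation (adjusted p = 0.531), the highest over the alternatives, where fry gave the lowest at 8.61e-04. All 13 endothelial genes were higher in the thyroid cells (median -7.28). The share of cells that are not epithelial in this difference was not separated. Cldn1, a tight junction gene, was at least 49.9-fold and Krt8 3.88-fold higher in thymic cells, and Tjp1 was 2.95-fold higher in thyroid cells.

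Chaperones of the endoplasmic reticulum and unfolded protein response genes were higher in thyroid cells in 18 of 21 members and higher in thymic cells in 0 (median -1.17, -0.96 on slide 1, camera adjusted p = 4.39e-06, and adjusted p = 0.371 with an estimated correlation). Dnajc3 was 4.72-fold and the disulfide isomerase gene Pdia6 3.65-fold higher there. Antioxidant and selenoprotein genes were higher in thyroid cells in 15 of 25 members and in thymic cells in 5 (median -0.59, -0.67 on slide 1, camera adjusted p = 0.00839). Quantile normalization (adjusted p = 0.206), a filter on all 6 arrays (adjusted p = 0.102) and an estimated correlation (adjusted p = 0.386) ended that call, in a range down to 7.96e-04 with fry. Gpx2 was 6.78-fold higher in thyroid cells, and Gpx3 11.3-fold higher in thymic cells. Immediate early and heat shock genes, which respond within minutes to handling and stress, were higher in thyroid cells in 12 of 17 members (median -0.82, -1.08 on slide 1, camera adjusted p = 0.00221). Quantile normalization (adjusted p = 0.0743) and an estimated correlation (adjusted p = 0.425) ended the call, in a range down to 2.36e-04 without thymic replicate 2. Ier3 was 6.33-fold and Nr4a1 5.13-fold higher. All 13 endothelial genes were higher in thyroid cells too (median -7.28). Their share in the chaperone, antioxidant and immediate early differences was not separated.

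**Figure D2:**
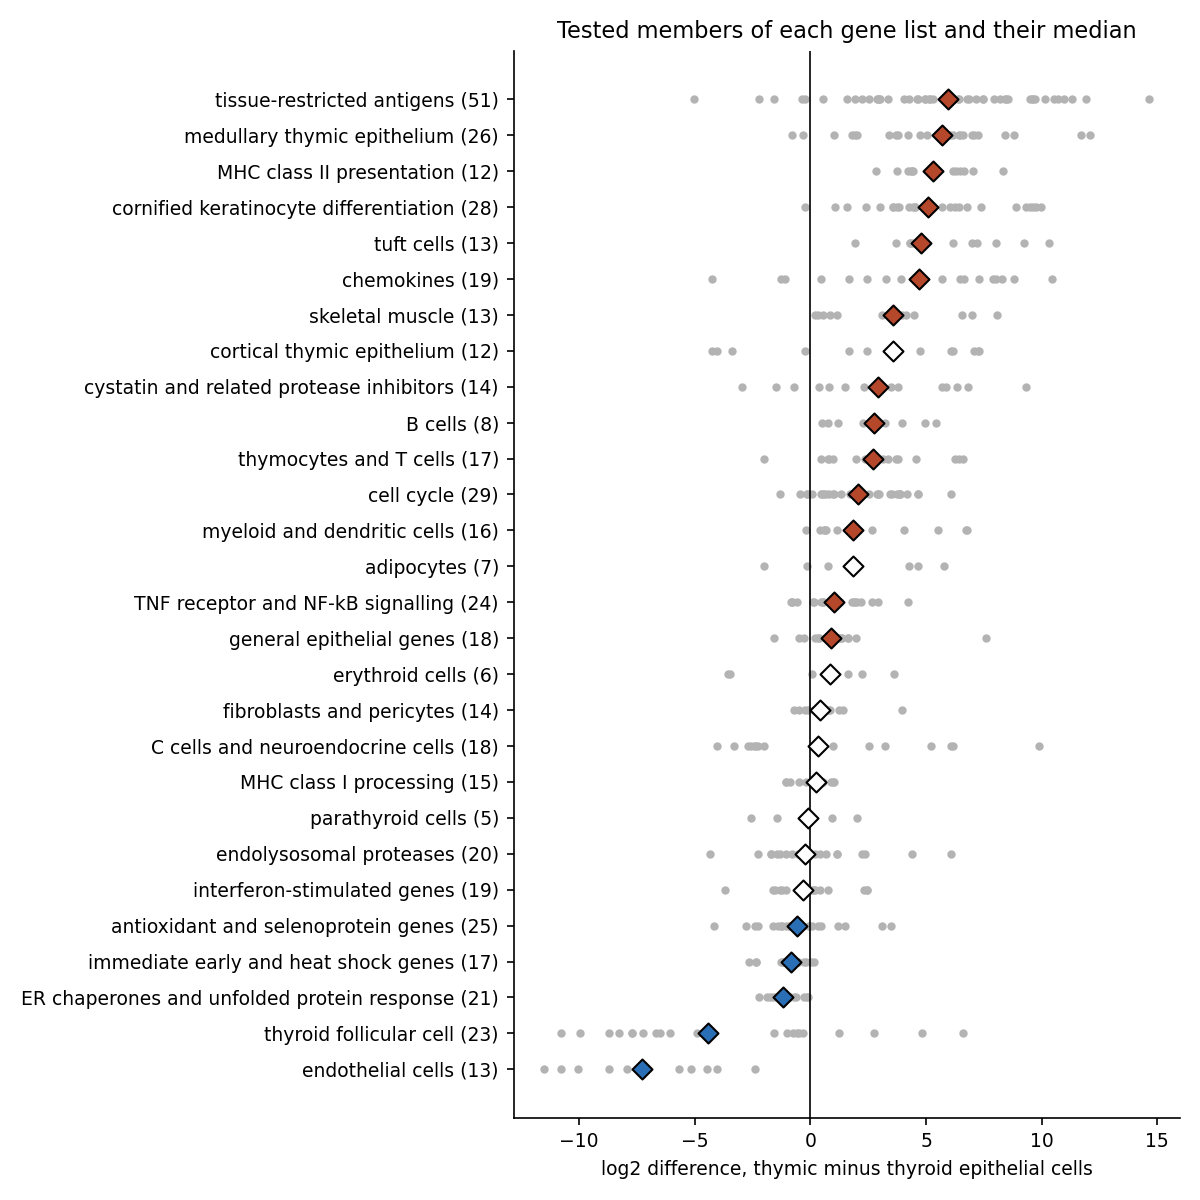
Log2 difference, thymic minus thyroid (horizontal axis), of every tested member (grey points) and the list median (diamonds) for 28 gene lists, with the number of tested members in brackets. Red and blue diamonds mark lists past a camera adjusted p of 0.05 towards thymic and thyroid cells, and white diamonds lists that did not pass; medians run from -7.28 for endothelial genes to 5.97 for tissue-restricted antigens.

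Genes of other cell types also differed. All 13 endothelial genes were higher in the thyroid cells (median -7.28, -7.42 on slide 1, camera adjusted p = 3.60e-09, and adjusted p = 0.263 with an estimated correlation). Emcn stood at 7.64 ± 0.36 in thyroid and -3.88 ± 0.03 in thymic cells, and Kdr, which encodes a receptor for vascular growth factor, at 7.12 ± 0.19 and -3.68 ± 0.19 (SD, n = 3). Thymocyte and T-cell genes were higher in thymic cells in 15 of 17 members (median 2.73, 2.81 on slide 1, camera adjusted p = 0.00139, and adjusted p = 0.410 with an estimated correlation), with Cd8a at least 31.7-fold and Rag1 at least 20.3-fold higher. Cd8a was at -1.67, -1.31 and -0.00 on the arrays of thymic replicates 1, 2 and 3. The list's 1 member higher in thyroid cells was Cd8b1, whose kept probe lies on chromosome 5 in the array files. The gene lies on chromosome 6. Without probes on another chromosome than their gene, Cd8b1 was higher in thymic cells, at a log2 difference of 6.59. Myeloid and dendritic genes were higher in thymic cells in 14 of 16 members (median 1.83, 1.93 on slide 1, camera adjusted p = 0.00145, and adjusted p = 0.386 with an estimated correlation), with Lyz2 107-fold higher. All 8 B-cell genes were higher in thymic cells (median 2.73, 2.87 on slide 1, camera adjusted p = 0.00508, and adjusted p = 0.249 with an estimated correlation), with Ms4a1 at least 13.6-fold. Skeletal muscle genes were higher in thymic cells in 11 of 13 members (median 3.59, 3.35 on slide 1, camera adjusted p = 0.00221, and adjusted p = 0.179 with an estimated correlation), with Actn3 127-fold higher, or 217-fold without thyroid replicate 2.

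The remaining lists did not pass by camera at the preset correlation. Fry called 3 of them, the C-cell, erythroid and adipocyte lists. Fibroblast and pericyte genes had a median of 0.42 (0.09 on slide 1, -0.12 with median centring, camera adjusted p = 0.669), with 4 of 14 members higher in thymic cells and 1 higher in thyroid cells. C-cell and neuroendocrine genes had 8 of 18 members in each direction (median 0.32, 0.10 on slide 1, -0.22 with quantile normalization, camera adjusted p = 0.840 towards the thyroid, in a range of 0.00787 with fry to 0.986). Calca, the calcitonin gene, was 16.5-fold higher in thyroid and its relative Calcb, above background on 2 thyroid arrays, at least 648-fold higher in thymic cells. Parathyroid genes had a median of -0.08 (-0.00 on slide 1, 0.00 with quantile normalization, camera adjusted p = 0.769), with Pth, the parathyroid hormone gene, 5.98-fold higher in thyroid cells (adjusted p = 0.0158, and 0.0859 on slide 1, in a range of 0.00294 to 0.173 with the slide as a block). Without thyroid replicate 2, Pth was 3.64-fold higher and the parathyroid median was 0.17. Erythroid genes had a median of 0.84 (0.82 on slide 1, camera adjusted p = 0.885, in a range of 0.0109 with fry to 0.981), with the haemoglobin genes Hbb-bt and Hba-a1 at -3.54 and -3.46, higher in thyroid cells. Adipocyte genes had a median of 1.82 (1.64 on slide 1, camera adjusted p = 0.246, in a range of 5.49e-05 with fry to 0.516), with Cidec 54.2-fold higher in thymic and Pparg 3.96-fold higher in thyroid cells.

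**Figure D3:**
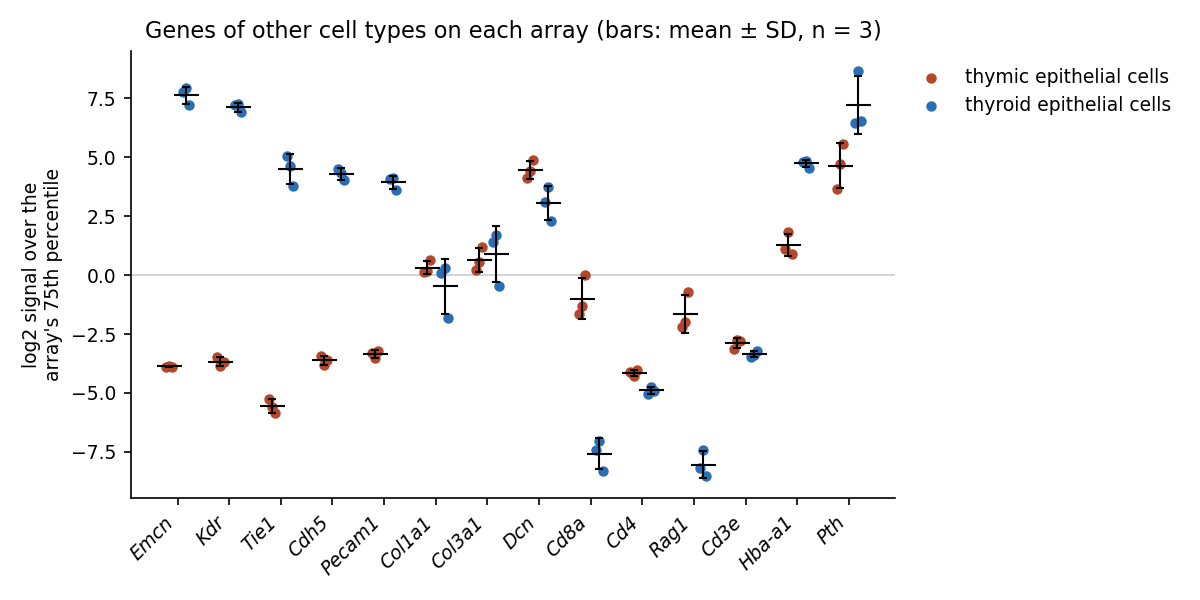
Log2 signal relative to the array's 75th percentile (vertical axis) of genes of endothelial, fibroblast, T, erythroid and parathyroid cells (horizontal axis), with 1 point per array in red for thymic and blue for thyroid cells and bars for the mean ± SD of 3 arrays. Emcn stands at 7.64 in thyroid and -3.88 in thymic cells, and Dcn at 3.06 and 4.46; Cdh5, Pecam1, Col1a1, Col3a1, Cd4 and Cd3e lie outside the naming rule and were chosen after their values were seen.

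Of 28 lists, 14 were higher in thymic and 5 in thyroid cells by camera at a preset correlation, and 0 passed with an estimated correlation, where fry called 24. With members set to their lower bounds, the medians were 5.20 for medullary, 5.05 for MHC class II, 4.58 for chemokine, 1.95 for B-cell and 0.56 for erythroid genes. Adjusted over the list alone, the counts of members equalled those over all genes except in 5 lists: 17 thyroid follicular genes higher in thyroid cells, 46 tissue-restricted antigens and 16 thymocyte genes higher in thymic cells, 3 general epithelial genes and 1 parathyroid gene higher in thyroid cells.

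More probes were detected on the thymic arrays. Of 41174 probes, 33351, 32603 and 32296 were well above background on the 3 thymic arrays and 28985, 26903 and 29952 on the thyroid arrays, means of 32750.0 ± 543 and 28613 ± 1558 (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). On slide 1, the single thyroid array had fewer than each of the 3 thymic arrays. Of 19750 genes with a current symbol, 13855 were above background on all 6 arrays, 1776 on all thymic and no thyroid arrays, and 76 on all thyroid and no thymic arrays.

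**Figure D4:**
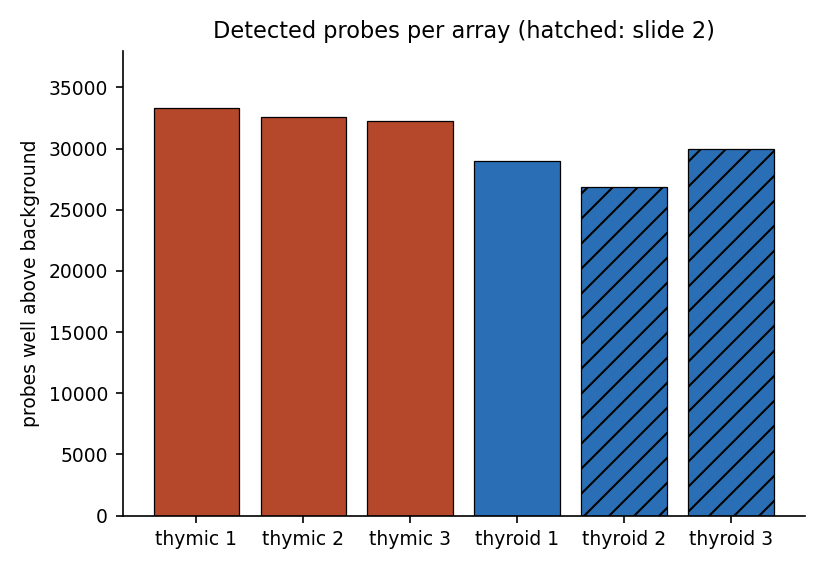
Number of probes well above background (vertical axis, from 0) on each of the 6 arrays, in red for thymic and blue for thyroid cells, with slide 2 hatched. The thymic arrays lie between 32296 and 33351, all above the thyroid arrays, which lie between 26903 and 29952.

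Arrays of a group resembled each other closely. Across tested probes, which are not independent replicates, Pearson's r was 0.993 to 0.995 between thymic arrays, 0.986 to 0.989 between thyroid arrays and 0.741 to 0.775 between the groups. The principal component that separated the groups held 95.8% of the variance.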

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

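Scaling by the median of commonly detected probes, leaving out both replicates 3 and leaving out probes on another chromosome than their gene were chosen after seeing the data; all other alternatives were planned. Median centring gave 11041 genes higher in thyroid cells, 5853 of them at 2-fold or more, and the deposited values gave 10966 and 5782. Both divide by the array's median, which lies lower under the 75th percentile on thyroid arrays (7.78 to 8.20 times against 5.47 to 5.60). Normexp gave 3573 genes at 2-fold or more towards the thymic cells; the cause was not tested. A filter on all 6 arrays leaves out genes detected in 1 group only and gave 5032 genes higher in thymic and 6403 in thyroid cells, 2758 and 2832 at 2-fold or more. With an estimated correlation, camera called 0 lists, where the preset correlation called 19. Fry turned the C-cell list (mean 0.76, median 0.32) towards the thymic cells. Fry compares no list with other genes, whereas camera does, so their directions can differ. Cd8b1 turned to 2.31 with the median over probes and to 6.59 without its probe on another chromosome; leaving out such probes gave 8396 and 6511 genes. Leaving out a replicate gave 7677 to 8389 genes higher in thymic and 5580 to 6391 in thyroid cells, with no count moved by over 1.5 times. Leaving out both replicates 3 gave 7818 and 5468, and scaling by commonly detected probes 8609 and 6273. With the replicate block, 8053 and 5997 genes passed, 6066 and 3140 at 2-fold or more, and 19 lists. The replicate numbers do not pair the arrays: same-numbered arrays deviated together with r of -0.07 to 0.01, and 0 of 3 thymic arrays correlated best with their own number. Of the values of single genes under an alternative, 2232 stayed on their side of the threshold with no call reversed, 39 lost the call, 4 gained it and 2 reversed. Of those of lists, 636 stayed likewise, 24 lost the call, 8 gained it and 1 reversed. Values that passed in neither setting count as staying even where their sign changed, as for Ctsl and the MHC class I, interferon, C-cell, parathyroid and fibroblast lists. Signal over background limits genes near the floor. Their folds are lower bounds, in the sense defined above, where arrays were not above background, and plain folds elsewhere.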

Other observations

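Chosen only after the results were seen were the tests of array brightness, of carry-over from stroma and blood, of the slide and of the thymocyte genes. So were the sex-linked genes and Pth, Chga, Col1a1, Psmb11, Prss16, Dcn, Lum, Col6a1 and Foxn1, named here as they varied between replicates. The other cortical and fibroblast genes listed below were also added after the values were seen. The remaining tests were set before their values were seen, but the written prediction of the spike-in test did not hold the SD used below.

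Sex-linked genes set thyroid replicate 3 apart. Xist, the RNA of the inactive X chromosome, stood at 4.56 on that array, at -7.50 and -7.29 on the other thyroid arrays, and between -5.29 and -4.95 on the thymic arrays. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were not well above background on that array and were well above background on the other 5, where Ddx3y lay between 0.88 and 1.95. These are the levels of a female pool on that array and of mainly male pools on the other 5, although the labels give no sex. If so, sex was not balanced between the groups, and thyroid replicate 3 lay on slide 2. Leaving out thyroid replicate 3 gave 8389 genes higher in thymic and 6391 in thyroid cells. Neuroendocrine and parathyroid genes varied between replicates: Pth was at 6.47, 8.66 and 6.55 in thyroid replicates 1, 2 and 3 and at 3.65, 4.71 and 5.57 in the thymic ones, and Chga at 6.39, 8.51 and 6.44 and at 4.23, 4.83 and 5.49. Col1a1 was at 0.10, 0.29 and -1.82 on the thyroid arrays. Pth, Chga and Col1a1 were singled out here for their spread.

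Genes detected on all thymic and no thyroid arrays lay next to each other more often than shuffles gave. Among 19746 genes in chromosome order, 209 neighbouring pairs with different symbol stems were both of this class, against a mean of 139 and a 95% range of 118 to 161 over 10000 shuffles. With the class shuffled only over the 4284 genes above background on no thyroid array, the mean was 136 and the range 116 to 157 (permutation p = 1e-04 for both, the smallest that the shuffles can give). A hypothesis is that thymic-only detection may extend over neighbouring genes. Gene families whose members carry unlike names were not removed, and they stay open as a source of such pairs.

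The larger number of probes detected on thymic arrays was weighed against 3 explanations. Blood and stromal cells in the thymic sort stay open. Of 53 tissue-restricted genes, 47.2% were detected on thymic arrays only, against 8.89% of other genes (Fisher's exact p = 4.49e-13). That met the prediction written against this cause. Genes detected on thyroid arrays cannot be of this class, and they make up most of the other genes. Of the 4284 genes above background on no thyroid array, 1776 were above background on all thymic arrays. The list was also chosen as genes of other organs, so the test cannot decide. Array brightness stays open. Thyroid replicate 1 had a higher 75th percentile than every thymic array and differed in detected probes from the thymic array with the fewest by -3311, but that is a single array, and the median signal was lower on the thyroid arrays (98.2, 61.1 and 90.5) than on the thymic arrays (139.7, 125 and 123). Weaker labelling of thyroid RNA cannot be told apart, because the brightest thyroid array exceeded the dimmest thymic array by 0.0103 on the log2 scale in spike-in signal, less than the SD of 0.10 among thymic arrays. The written prediction against this explanation asked only for a thyroid array as bright as the dimmest thymic array, and it was met. The SD was not part of that prediction. Broad antigen expression in the medulla, the biological difference between the groups, stays open.

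The endothelial genes on the thyroid arrays were weighed with another list of 16 endothelial genes, written before its values were seen and sharing no gene with the fixed lists. All 16 were higher in the thyroid cells, with a median of -4.51, so endothelial cells or their RNA in the thyroid sort are a candidate explanation, although the gate required Epcam. The members of the fixed list with the brightest probes, which do not rank abundance, were Emcn, Flt1 and Kdr and lay between 6.90 and 8.20 on the thyroid arrays. General carry-over of stroma and blood stays open. The lowest median among fibroblast, myeloid, T-cell and B-cell lists was 0.42, for the fibroblast list, which did not pass and turned to -0.12 with median centring. The blood-cell lists are set against a thymic sort in which they are higher, and haemoglobin genes were higher in the thyroid cells. The slide is argued against, with a median of -7.42 on slide 1.

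Thymocyte genes on the thymic arrays may come from thymocytes in the sort, which the CD45 gate should remove, or from the medullary cells. None of the 17 detected list members belongs to another fixed list. Of these members, 82.4% were highest in thymic replicate 3, the pool of 2 thymi, against 36.0% of other genes (Fisher's exact p = 1.23e-04), as thymocytes in that pool would give. The tissue-restricted list, which holds no T-cell genes, behaved alike at 80.4% (Fisher's exact p = 1 between the lists, and 1.01e-10 against other genes), so the test does not single out thymocytes and the explanations cannot be told apart. The written prediction was met, and the comparison with the tissue-restricted list was made a condition only after the values were seen. Genes on an array are not independent, and replicate 3 is a single array. These p-values therefore do not measure variation between replicates. Many cortical and fibroblast genes were highest in replicate 3 too. Psmb11 was at 0.80, 1.82 and 2.75 in thymic replicates 1, 2 and 3, Prss16 at 2.28, 3.35 and 4.07, Dcn at 4.10, 4.42 and 4.87, and Lum at -0.88, 0.05 and 0.76. Tbata, Ly75, Ccl25, Cxcl12, Kitl, Col1a1, Col1a2, Col3a1, Col6a3, Pdgfra, Pdgfrb, Postn and Thy1 were also highest there. Lowest there were Il7, Fn1, Rgs5, Acta2, Col6a1 (2.54, 2.62 and 1.85) and Foxn1 (1.36, 1.55 and 1.25), which the medullary list shares. Ctsl was highest in replicate 2. The median excess of replicate 3 over the other thymic arrays was 0.61 for the thymocyte and 0.29 for the tissue-restricted list. The members with the brightest probes in replicate 3, Dntt, Tcf7 and Lck, were at 1.40, 0.49 and 0.29, which do not rank abundance.

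The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 14917 genes past the threshold, and 1 split, the real one, gave as many. The highest of the others was 0 by limma at an adjusted p under 0.05, with 38 to 99 genes at an unadjusted p under 0.05. Every other split puts arrays of both groups on each side. The difference between the groups then widens the spread within a side, so these low counts decide nothing about chance.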
